A study of Mus musculus with 7 samples.

How the data were processed

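Total RNA was extracted from dissected RPE with the miRNeasy kit and labelled with biotin for Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of log2 signals for the 7 arrays, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes arrays to a common distribution by quantiles and summarizes probes) and Partek 6.6, without saying what each did. The log2 scale was read from the values, which ran from 2.71 to 13.5. The genome build, the alignment of probes and any filter are not given in the sources used here. Normalization by quantiles would remove differences in the total amount of RNA, and the deposited arrays still differed in distribution, with control 4 at a median of 6.05 and the others at 6.22 to 6.26.

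The table held 65535 rows, which is the row limit of older spreadsheet files, each a probe set for part of a gene (about an exon) and not for a whole gene, as had been assumed when the design was fixed. The test was kept as fixed. By the platform annotation, 53644 probe sets had 1 gene symbol, 877 had several and 11014 are unnamed here, and the first kind gave 5017 genes with a median of 8 probe sets, 547 of them with 1. Symbols were brought up to date with the RefSeq gene table of mouse, which was also used for the chromosome and order of genes but not for coordinates: 4315 were current, 689 were updated and 13 were kept unmatched. The genes measured include 86.11% of the protein-coding genes of chromosomes 1, 10, 11, 12 and 13 and 21.31% of all protein-coding genes, and the rest of the genome was not analysed here. No detection calls were used here.

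Groups came from the labels, 4 control and 3 Dicer1-deficient arrays, and replicate numbers are names only and pair no arrays. The sample labels call the controls only control RPE and do not state their genotype. The labels give no batch that differs between the arrays. Per gene, the probe set with the highest mean over the 7 arrays was used with no filter on dim genes, and groups were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). The moderation had 2.82 prior and 5 residual degrees of freedom. A fold change is Dicer1-deficient minus control on the log2 scale, and errors of group means are SDs over arrays. For probe sets of Dicer1, p was also adjusted over its 28 probe sets.

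Before the data were examined, 34 gene lists were fixed from textbook knowledge, with a further list of microRNA precursor genes that had no measured member. The 15 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, with camera at an estimated correlation and fry as alternatives. For each list the members past the threshold were counted over all genes and with p adjusted over the list alone. The genes named are Dicer1, the 12 highest and 12 lowest fold changes among genes past the threshold whose arrays do not overlap (leaving out symbols such as those ending in Rik that name no characterised gene), and up to 4 members per list with the smallest p. Alternatives fixed in the same way were quantile normalization again, median centring, filters on dim genes, all probe sets or their mean per gene, a variance trend, robust or no moderation, array weights, other thresholds, a covariate of retinal markers and leaving out each array. The mean of probe sets without control 4 was added after the data were seen.

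The same code was tested on simulated data with the 5017 genes, the group sizes and 200 changed genes, in 20 simulations. It recovered 33.3% of genes changed by 0.5 on the log2 scale, 74.2% at 1, 96% at 2 and 98.9% at 3. Of its calls, 5.05% were false. A list whose members were all shifted by 0.5 was called in 20 of 20. The simulated noise was independent between genes and had the same SD in every array for a gene. It held no array like control 4 and no correlation between genes, so these rates may not hold for the real arrays. Work was done in R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.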

Results

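The series measured messenger RNA in retinal pigment epithelium (RPE), the pigmented cell layer behind the photoreceptors, dissected from mouse eyes at postnatal day 5. It held 7 Affymetrix arrays in 2 groups, 4 of control RPE and 3 of Dicer1-deficient RPE. Dicer1 encodes the enzyme that cuts microRNA precursors into mature microRNAs, and the deficient genotype carried floxed Dicer1 on both alleles with a Cre transgene under the dopachrome tautomerase promoter, which is active in pigment cells. The series title and design text ask what loss of Dicer1 does to the RNA of the RPE and to the differentiation of this tissue. The values were log2 signals, with a median of 6.22 over all probe sets and arrays and a range from 2.71 to 13.5. They covered 5017 genes, 4918 of them on chromosomes 1, 10, 11, 12 and 13, so that many well-known RPE genes (Rpe65, Tyr, Mitf and Best1 among them) were not analysed here. Nothing in the labels says whether the arrays came from separate animals, so p-values measure the spread between these samples, which may be partly technical, and the small number of arrays limits the precision.

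Controls 1 to 3 and the 3 Dicer1-deficient arrays each formed a tight set, and control 4 stood apart from both. Pearson correlations across all probe sets, which are not independent replicates, ran from 0.986 to 0.988 among controls 1 to 3 and from 0.980 to 0.984 among the Dicer1-deficient arrays. Control 4 correlated with the other 6 arrays at 0.943 to 0.951. Its median signal was 6.05, against 6.25 to 6.26 in controls 1 to 3 and 6.22 to 6.26 in the Dicer1-deficient arrays. The first principal component took 42.9% of the variance and ran from control 4 to the Dicer1-deficient arrays.

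**Figure D1:**
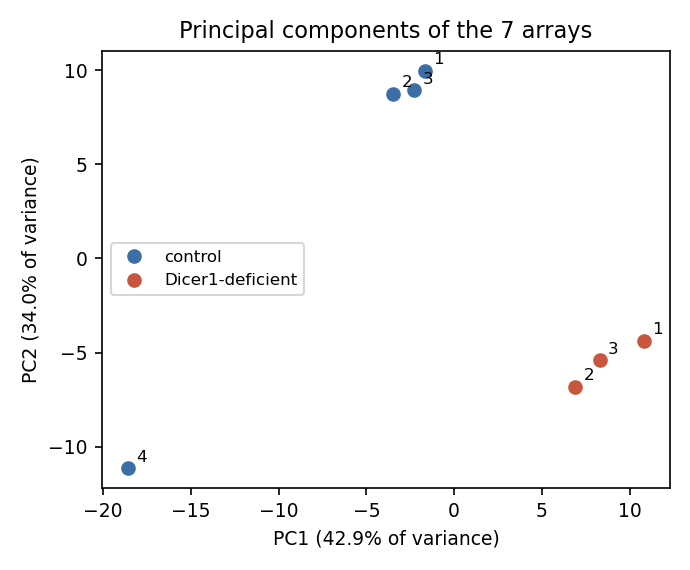
First and second principal components of the 7 arrays (axes in component units, with the share of variance of each), 1 point per array, coloured by group and numbered by replicate. Control 4 lies at -18.6 on the first component, the other controls between -3.47 and -1.69 and the Dicer1-deficient arrays between 6.91 and 10.8.

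The signal of the targeted gene was nearly level between the groups. Dicer1, on chromosome 12, had a log2 signal of 10.62 ± 0.26 (SD, n = 4) in control and 10.57 ± 0.13 (SD, n = 3) in Dicer1-deficient arrays at its brightest probe set, a log2 fold change of -0.05 (SE 0.15; limma, Benjamini-Hochberg adjusted p = 0.961). The controls read 10.27, 10.65, 10.69 and 10.88, and the Dicer1-deficient arrays 10.53, 10.71 and 10.47. Of its 28 probe sets, 14 were lower in the Dicer1-deficient arrays, and their median log2 fold change was -0.00246. Only probe set 10402447 passed the test when limma's p was adjusted over the Dicer1 probe sets, at 6.31 ± 0.15 against 5.52 ± 0.23, a log2 fold change of -0.78 (adjusted p = 0.0293). Without control 4, probe set 10402463 also passed, with a log2 fold change of -1.59 (adjusted p = 0.0321), against -0.92 with that array. The labels do not say which part of Dicer1 is floxed, and a probe set outside the deleted part checks nothing about the genotype.

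**Figure D2:**
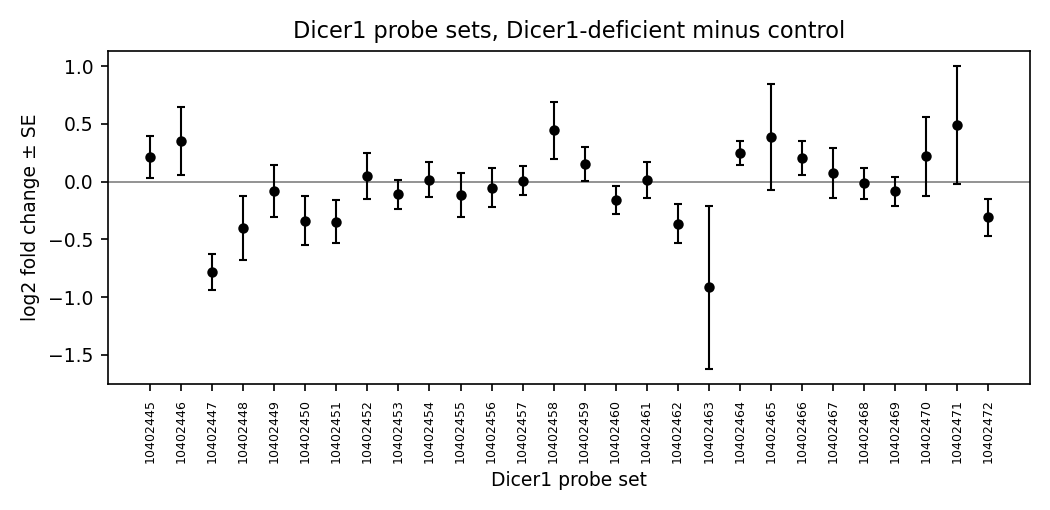
Log2 fold change (Dicer1-deficient minus control) of each of the 28 Dicer1 probe sets, in order of probe set number, with bars of 1 standard error from limma. The points scatter around 0, with 14 of 28 below it, and probe set 10402447 at -0.78 is the one past the test adjusted over these probe sets.

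The dissected Dicer1-deficient RPE carried a small set of large changes in both directions. Whether RPE cells or other cells of the samples carried these changes was not tested. The largest was Nyap2, a neuronal adaptor of phosphoinositide 3-kinase, whose log2 signal was 5.19 ± 0.26 (SD, n = 4) in control and 10.79 ± 0.11 (SD, n = 3) in Dicer1-deficient arrays at its brightest probe set, 48.6-fold higher. Its control signal was below the median of all probe sets and was not shown to be above background, so that fold is at best a lower bound for the probe set, and the mean of its 8 probe sets gave 3.31 on the log2 scale. The largest fall was that of Tshr, the thyrotropin receptor, from 11.27 ± 0.50 to 7.54 ± 0.23, 13.3-fold lower, and Trhde, an enzyme that degrades thyrotropin-releasing hormone, fell from 8.59 ± 0.20 to 6.18 ± 0.55. The ubiquitin ligase gene Trim9, the synaptic endocytosis gene Amph and Irx4, a homeobox gene of the heart ventricle, rose. The control signal of Trim9 (6.15) and the Dicer1-deficient signal of Trhde (6.18) were just below the median of all probe sets (6.22). Neither was shown to be above background, so these folds are at best lower bounds too.

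By limma with Benjamini-Hochberg adjustment over all 5017 genes, 117 genes (2.33%) passed adjusted p of 0.05, 71 higher and 46 lower in Dicer1-deficient RPE. In all 117 the arrays of the groups did not overlap, which held for 16.28% of all genes where chance gives 5.71%. A fold of at least 2 was reached by 29 of the higher and 17 of the lower genes. The limma adjusted p was 2.5e-06 for Nyap2 (log2 fold change 5.60, SE 0.15), 6.5e-04 for Tshr (-3.74, SE 0.27) and 0.0031 for Trhde (-2.40, SE 0.25). Trim9 rose by 2.59 on the log2 scale (limma adjusted p = 0.0212) and Amph by 1.99 (0.0178). Irx4 rose by 2.39 (limma adjusted p = 3.9e-04) from a control signal of 4.51 ± 0.05, which is below the lower quartile of all probe sets (4.63) and was not shown to be above background, so its fold is at best a lower bound.

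Among the other genes that rose most were Otx1, a homeobox gene of the developing forebrain and eye (6.32 ± 0.39 to 8.22 ± 0.15, log2 fold change 1.90, limma adjusted p = 0.0044), and Acss3, a mitochondrial acyl-CoA synthetase gene (log2 fold change 1.74). Otogl, which encodes an otogelin-like matrix protein of the inner ear, rose by 1.73, Mogat1, a monoacylglycerol acyltransferase gene, by 1.58 and Aspa, the gene of aspartoacylase, by 1.49. Pld5 (8.11 ± 0.49 to 9.93 ± 0.09) and Cabcoco1 (1.64) rose too. The control signal of Cabcoco1 (6.19) was just below the median of all probe sets (6.22) and was not shown to be above background, so its fold is at best a lower bound. Esr2, the gene of estrogen receptor beta, rose by 1.64 at its brightest probe set from a control signal of 5.08 ± 0.18. That signal was below the median of all probe sets and was not shown to be above background, so the fold is at best a lower bound for the probe set. On the mean of the 12 probe sets of Esr2 the log2 fold change was 0.34 (limma adjusted p = 0.0807).

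Of the genes that fell most, Adam23 (-1.88) and Itgb8 (-1.31) encode proteins of cell adhesion, the latter an integrin subunit that activates latent TGF-beta. Madcam1, a vascular addressin gene, fell by 1.88 on the log2 scale to 4.65 ± 0.08, near the lower quartile of all probe sets, so its fold is also at best a lower bound, and Ccl11, the eotaxin gene, fell by 1.29. Ankfn1 (-1.93), Nsg2 (-1.50) and Tmem229b (-1.42) fell, as did Chil1 (-1.89), which encodes a chitinase-like secreted protein. Nsg2 fell to 5.28 ± 0.14, below the median of all probe sets and not shown to be above background, so its fold is at best a lower bound too. The potassium channel gene Kcnh5 (-1.37) and Wfikkn2 (-1.28), whose product binds growth factors of the TGF-beta family, completed the 12. Limma's adjusted p for these 10 genes ran from 6.5e-04 to 0.032.

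With 1 array left out at a time, limma called 62, 46 and 64 genes without controls 1, 2 and 3, 33, 45 and 44 without Dicer1-deficient arrays 1, 2 and 3, and 260 without control 4 (116 of them among the 117), and 17 of the 35 named genes past the threshold stayed past it each time: Nyap2, Irx4, Otx1, Acss3, Otogl, Cabcoco1, Esr2, Tshr, Trhde, Ankfn1, Adam23, Madcam1, Nsg2, Itgb8, Wfikkn2, Kcnj13 and Arid3a. The count was 294 on the mean of each gene's probe sets, which shared 95 of the 117, and 385 with array weights. On that mean without control 4 it was 853 (338 higher and 515 lower, the reverse balance). With the mean of retinal neuron and photoreceptor markers as a covariate it was 28. Under that covariate the same 17 named genes passed and the other named ones, Trim9 and Amph among them, did not. The covariate included Tfap2a, itself 1 of the 35, and Tfap2b, so these genes were adjusted in part for themselves. Passing or failing under it therefore does not show whether retinal cells were carried over. On the mean of probe sets the log2 fold changes of several named genes were smaller by over 1.5 times: Nyap2 (3.31), Trim9 (0.88), Otx1 (1.17), Madcam1 (-1.19), Nsg2 (-0.52), Tmem229b (-0.79) and Mycn (0.52), with all of these still past the limma test, while Igf2bp1 was larger (1.90).

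**Figure D3:**
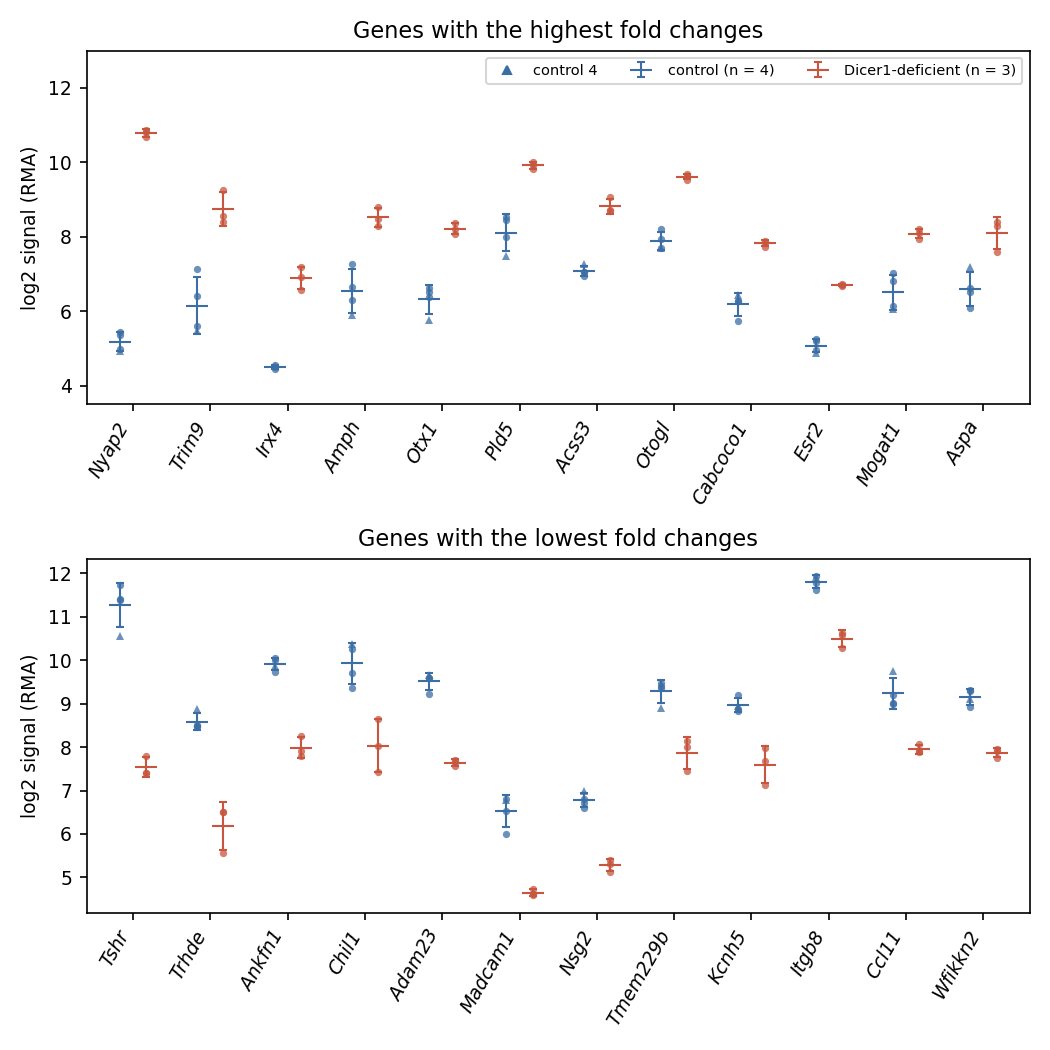
Log2 signal of the 12 genes with the highest and the 12 with the lowest fold changes, 1 mark per array (control 4 as a triangle), with the mean as a dash and bars of 1 SD for 4 control and 3 Dicer1-deficient arrays. Nyap2 moves from 5.19 to 10.79 and Tshr from 11.27 to 7.54. In none of the 24 genes do the groups overlap, which was a condition of their choice.

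Genes of RPE identity and function moved in part. Kcnj13, the gene of the Kir7.1 potassium channel of the apical RPE membrane, fell from 11.18 ± 0.16 to 9.99 ± 0.21 (log2 fold change -1.19, SE 0.14, limma adjusted p = 0.0051), and Atp1b1, a sodium pump subunit gene, rose by 0.62 (adjusted p = 0.047). These were the 2 of 8 measured members of the RPE transport, phagocytosis and secretion list to pass. Adjusted over the list alone 1 rose and 2 fell, the added member being Sulf1 at -0.43, which passed over all genes on the mean of its probe sets (-0.84, limma adjusted p = 0.0038) and without control 4 (-0.44, adjusted p = 0.029). Serpinf1, the gene of the secreted factor PEDF, had a log2 fold change of -0.23 (limma adjusted p = 0.399), and the list as a whole had a median of -0.16 (camera adjusted p = 0.143).

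Pigment genes lay lower in part of the Dicer1-deficient arrays. All 5 measured members of the melanin and melanosome list had negative log2 fold changes, with a median of -0.60: Mreg at -0.87, Slc24a4 at -0.69, Mlph at -0.60, Tspan10 at -0.28 and Pmel at -0.05. None passed the limma test on its own, over all genes or adjusted over the list alone. The list shift passed camera with a preset correlation of 0.01 (adjusted p = 0.0443 over the 15 lists tested), and it did not with an estimated correlation (adjusted p = 0.558 with an estimated correlation); no other list passed camera with either. The list mean was 9.93 in Dicer1-deficient array 1, inside the control range of 9.89 to 10.31, and 9.42 in both others, and without array 1 the camera adjusted p was 0.000907. The call was lost without control 2 (0.0688), control 3 (0.0831) or Dicer1-deficient array 3 (0.0627), and on the mean of probe sets Tspan10 had a log2 fold change of 0.04. The melanocyte and Schwann cell list lay lower too, with all 3 measured members negative and a mean of -0.61 (Pax3 at -0.90, Erbb3 at -0.59 and Cdh19 at -0.34). Without control 4 these were -0.88, -0.56 and -0.14. Melanocytes share the pigment genes with the RPE.

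Of the visual cycle genes, 3 retinol dehydrogenases were measured. Rdh10 went from 11.47 ± 0.09 to 11.11 ± 0.15 (log2 fold change -0.37, limma adjusted p = 0.159) and Rdh5 from 11.20 ± 0.15 to 10.82 ± 0.11 (-0.38, adjusted p = 0.178), with Rdh11 at -0.14. None passed over all genes, and 2, Rdh10 and Rdh5, fell when adjusted over the list alone. On the mean of probe sets both passed limma over all genes, Rdh5 at -0.72 (adjusted p = 0.0061) and Rdh10 at -0.54 (adjusted p = 0.0383). Of the RPE transcription factors measured, Otx1 rose as given above and Sox9 had a log2 fold change of 0.24 (adjusted p = 0.351), with 1 past adjusted over the list alone. Neither measured junction gene passed, with F11r at 0.15 and Tjp3 at -0.21. The sign of Tjp3 turned without control 4 (0.04) and on the mean of probe sets (0.15).

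Described targets of let-7, a microRNA family of differentiated cells, included 3 of the clearer rises. Arid3a went from 6.97 ± 0.12 to 8.30 ± 0.10 (log2 fold change 1.33, limma adjusted p = 0.0010), Igf2bp1, an oncofetal RNA-binding protein gene, from 7.40 ± 0.24 to 8.49 ± 0.07 (1.09, adjusted p = 0.0090) and Mycn from 5.74 ± 0.21 to 7.03 ± 0.36 (1.30, adjusted p = 0.0155). The control signal of Mycn was below the median of all probe sets (6.22) and was not shown to be above background. The same 3 of the 10 measured members rose when adjusted over the list alone, and none fell. The other members lay near 0, with Hmga2 at -0.11 and Lin28b at -0.30. Lin28b read 4.76 ± 0.36 in control and 4.46 ± 0.25 in Dicer1-deficient arrays, near the lower quartile of all probe sets (4.63). It was not shown to be above background. On the mean of probe sets without control 4, 4 members rose and 1 fell over all genes. The list's median was -0.01 while its mean, 0.31, and camera's direction were positive (camera adjusted p = 0.118).

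Of 6 measured described targets of miR-204 or miR-211, microRNAs abundant in RPE, none passed over all genes. Adjusted over the list alone 2 rose, the homeobox gene Meis1 at 0.63 and Sox11 at 1.07, and 1 fell, Efnb3 at -0.50 (limma adjusted p over all genes = 0.0735, 0.152 and 0.234). On the mean of probe sets Meis1 passed over all genes (0.54, limma adjusted p = 0.0436). Without control 4, which read low for this list, Sox11 passed over all genes (log2 fold change 0.76, adjusted p = 0.0052). The camera adjusted p of the list was 0.429. The microRNA machinery genes Ddx5 (0.03) and Tnrc6c (-0.09) and the microRNA host transcripts Meg3 (-0.16), Rian (-0.24) and Nova1 (0.11) did not pass. No microRNA precursor gene was among the genes measured.

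**Figure D4:**
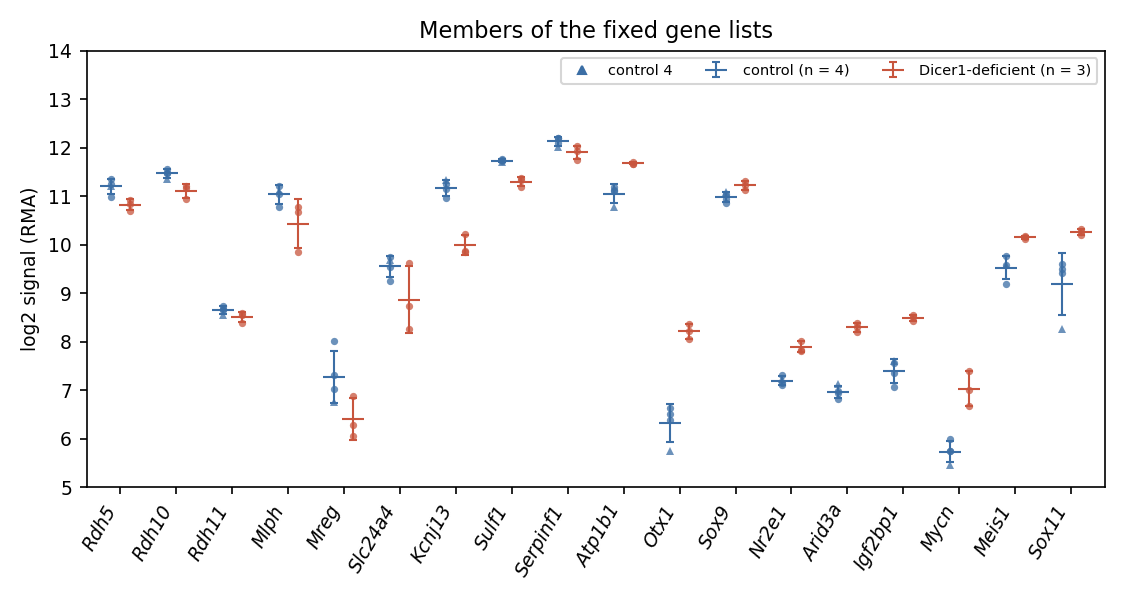
Log2 signal of 18 members of the gene lists fixed before the data were examined, 1 mark per array (control 4 as a triangle), with the mean as a dash and bars of 1 SD for 4 control and 3 Dicer1-deficient arrays. From left to right they are visual cycle, melanin, RPE transport, transcription factor, let-7 target and miR-204 or miR-211 target genes, with Nr2e1 of the retinal progenitor list between; Kcnj13 lies lower and Otx1, Nr2e1, Arid3a, Igf2bp1 and Mycn higher in Dicer1-deficient RPE.

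Markers of other ocular cells gave few calls at the brightest probe sets. Only 1 to 9 genes of each list were measured and 2.33% of all genes passed, so few calls do not show similar cell content. Some markers read high in control arrays, such as Col3a1 (13.18), Dcn (12.83) and Myh8 (11.12), beside Pmel of the melanin list at 12.66. Others read low, such as Rcvrn (4.86) and Atoh7 (5.78). RNA of other cells may thus be part of the signal, and a change cannot be assigned to RPE cells. Of the retinal progenitor list, Nr2e1, an orphan nuclear receptor gene, rose from 7.20 ± 0.09 to 7.90 ± 0.11 (log2 fold change 0.69, limma adjusted p = 0.0155), 1 of 4 measured over all genes and adjusted over the list alone, though not on the mean of its probe sets (0.45, adjusted p = 0.0758). Neurod4, of the same list, had a larger but variable difference of 1.83 (adjusted p = 0.325). In the inner retinal neuron list Tfap2a fell by 0.99 on the log2 scale (adjusted p = 0.047) while Tfap2b, its paralog, had a log2 fold change of 0.86 (adjusted p = 0.0938); adjusted over the list alone, 1 rose and 1 fell. Of 7 photoreceptor genes 6 had positive values, led by Pde6g at 1.38 and Rp1 at 0.76. The list median was 0.22, with none past the test either way (camera adjusted p = 0.143). Control signals of Pde6g (5.82) and Rp1 (5.26) were below the median of all probe sets (6.22) and were not shown to be above background. Lens genes had a median of 1.23 with wide spread, such as Cryba1 at 7.01 ± 1.69 and 8.97 ± 1.66, and none of the 7 passed either way (camera adjusted p = 0.118).

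Fibroblast and scleral genes had a median of -0.14 over 9 members, none past over all genes, and 2 fell adjusted over the list alone, Omd at -0.92 and Fmod at -0.60 (camera adjusted p = 0.0754, and 0.00107 on the mean of probe sets; adjusted p = 0.419 with an estimated correlation). In the melanocyte and Schwann cell list Pax3 (-0.90, limma adjusted p = 0.0639) and Erbb3 (-0.59, adjusted p = 0.0669) were the 2 of 3 that fell adjusted over the list alone. On the mean of probe sets these 4 passed limma over all genes, with Omd at -0.57 (adjusted p = 0.042), Fmod at -0.82 (0.024), Pax3 at -0.91 (0.0034) and Erbb3 at -0.39 (0.017). Of 4 macrophage genes Cd68 (-0.46) alone fell adjusted over the list alone. No member of the Mueller glia (6 measured), endothelium (2), erythrocyte (1), extraocular muscle (3) or surface epithelium (4) lists passed in either way of adjusting, with Glul at 0.14, Pecam1 at -0.10, Slc4a1 at -0.18, Myh3 at -0.02 and Krt12 at -0.07. The Mueller glia list had a camera adjusted p of 0.693 and the inner retinal neuron list 0.908.

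Signalling and stress lists changed in single members. Znrf3, a ubiquitin ligase gene that limits Wnt receptors, rose by 0.54 and Wif1, which encodes a secreted Wnt inhibitor, fell by 1.10 on the log2 scale (limma adjusted p = 0.0338 for both), and Znrf3 did not pass on the mean of its probe sets (0.44, adjusted p = 0.107). Adjusted over the list alone Tcf7 (0.52) rose with Znrf3 and Wif1 fell. The 7 measured Wnt genes had a median of 0.35 and a mean of -0.01, with camera's direction positive (adjusted p = 0.48). Etv5, a transcription factor gene induced by FGF, fell by 0.86 (limma adjusted p = 0.0173), and Dusp6, an FGF-induced phosphatase gene at -0.42, joined it adjusted over the list alone, 2 of 5 BMP, TGF-beta and FGF genes (list median -0.27, camera adjusted p = 0.0519). Etv5 lies on chromosome 16, of which only 3 of 679 protein-coding genes were measured. Its fold change was identical on the mean of probe sets, so no other probe set bears on it. Whether its signal comes from Etv5 alone was not checked. Perp, a p53 target gene whose product lies in desmosomes, rose by 0.91 (limma adjusted p = 0.0164), the 1 of 7 p53 and apoptosis genes to pass over all genes and adjusted over the list alone (camera adjusted p = 0.48).

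Fry's mixed test asks whether the genes of a list change in either direction and does not compare them with other genes. Its adjusted p was 3.5e-05 for the RPE transport list, 3.6e-06 for let-7 targets, 4.7e-04 for miR-204 or miR-211 targets and for Wnt genes, and 3.0e-04 for p53 genes. It was 0.0054 for epithelial-mesenchymal transition, 0.0103 for BMP, TGF-beta and FGF genes and 0.0385 for fibroblast genes, and the melanin list (0.0934) and the other 6 lists tested did not pass.

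The remaining lists held no gene past the limma test over all genes. The cell cycle genes, with Top2a at 0.16 and Cdk1 at 0.21, had 0 of 8 past in either way of adjusting (camera adjusted p = 0.502), and the integrated stress and unfolded protein response genes 0 of 6, with Dnajb9 at 0.40 and Ddit3 at 0.48 (camera adjusted p = 0.559). Among 6 genes of epithelial-mesenchymal transition 1, Twist1 at -0.57, fell adjusted over the list alone, with Fn1 at -0.22 (camera adjusted p = 0.151). Of 4 glycolysis and hypoxia genes 1, Pgk1 at 0.40, rose adjusted over the list alone. Pgk1 lies on chromosome X, of which only 6 of 966 protein-coding genes were measured, and whether its probe sets read Pgk1 alone was not checked. None passed in either way among 4 interferon (Rsad2 at 0.80), 2 inflammasome and cytokine (Nlrp3 at 0.14) and 2 cholesterol synthesis genes (Idi1 at -0.30). The same held for 3 oxidative phosphorylation (Atp5b at 0.20), 3 lysosome (Psap at -0.24) and 3 immediate early genes (Fos at -0.51). With control 4 left out, Rsad2 was at 0.41, Fos at -0.06 and Nlrp3 at 0.24. Of the named list members not past the test over all genes, 16 passed limma on the mean of probe sets, those not given above being Sox9 (0.33), Tfap2b (0.81), Dnajb9 (0.50), Twist1 (-0.56), Tgfb2 (0.51), Fn1 (-0.44), Pfkp (0.46) and P4ha1 (-0.39). Without control 4, 7 did, Sulf1 and Sox11 with Twist1 (-0.65), Tcf7 (0.49), Rnf43 (0.73), Dusp6 (-0.51) and Pgk1 (0.44).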

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

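Of the tests in this part, the splits of the arrays and the share of variance between genes were chosen before their results were seen, and the tests on cell type lists, on the slope of control 4 and on Nyap2 were chosen after. The criterion for the neighbours of Nyap2 was also changed after its result was seen: at first 1 of 20 past the threshold was enough to exclude a change of the neighbourhood, and now none may pass, at an adjusted p of 0.1 either, which left that explanation open.

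Among 52 values examined in the 4 controls (chance marks about 1 in 20), 6 had an array far from the other 3, and in 5 of them it was control 4. Its median over all probe sets was 6.05, against 6.249 to 6.263 in the others. Its mean was 10.93 for the RPE transport list (others 11.09 to 11.11) and 9.226 for the miR-204 or miR-211 target list (others 9.651 to 9.7). It read 8.885 for Trhde (others 8.458 to 8.511) and 8.442 for Wif1 (others 7.861 to 7.954). Control 1 read 9.232 for Adam23, against 9.596 to 9.656 in the others.

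Control 4 may stand apart in part because of a compressed signal, as a hypothesis, and a part played by noise in single probe sets was not decided. Of the variance of its deviations from controls 1 to 3, a share of 0.134 lay between genes (95% interval over resampled genes 0.124 to 0.142). That was below the Dicer1-deficient arrays (0.312 to 0.438), so the criterion set beforehand for noise was met. It was above controls 1 to 3 (0.0437 to 0.105). Each of those was set against the mean of the others among controls 1 to 3. That mean held fewer arrays than the one used for control 4, so these shares, and the SDs below, are not strictly comparable. A low share was thus seen in every control, and that of control 4 was the highest as computed. The share therefore cannot decide whether noise in single probe sets set control 4 apart. The deviations of control 4 were larger, with an SD of 0.661 against 0.300 to 0.315 for controls 1 to 3. Its slope over genes on the mean of controls 1 to 3 was 0.881, against 0.994 to 1 for each of those controls on the mean of the other two. Other cells in the sample cannot be told apart from this, since the largest mean deviation of a cell type list was 0.861, for the lens, whose list mean also ran from 5.91 to 7.61 among the other controls. The design gives no difference among controls, so no biological explanation was tested.

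The 117 genes past the threshold were not matched by any other split. Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, gave as many, and the highest of the others gave 1 gene. That is the smallest outcome 35 splits can give, so it argues against chance as the source of the count but cannot exclude it. Without control 4, 10 splits remain, too few for a share under 0.05, and the real one gave 260 genes and the highest other 0.

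The rise of Nyap2 was argued against as an artefact of single probe sets, and its source stays open. Single cross-hybridising probe sets would leave most of its 8 probe sets unmoved, yet in 8 of 8 every Dicer1-deficient array lay above every control, with differences of the group means from 1.34 to 5.60 on the log2 scale. A change of its whole chromosome neighbourhood, such as an inserted transgene or a linked variant, would move several neighbours, and of the 20 nearest measured genes 1, Ap1s3, passed the threshold (log2 fold change 1.37), with 3 past an adjusted p of 0.1, Mrpl44 (log2 fold change 0.52) and Col4a4 (0.64) being the others. Over all 5017 genes 117 (2.33%) passed the threshold and 213 an adjusted p of 0.1, so some neighbours can pass without such a change. The counts are too few to show such a change and, under the criterion that none may pass, too many to exclude one. Such a change therefore cannot be told apart from an effect of Dicer1 loss on Nyap2, or from an event at Nyap2 alone.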

How the results depend on the processing

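The mean of probe sets without control 4 was chosen after the data were seen, and all other settings before. All 35 named genes past the threshold kept their direction in each fit that left out 1 array. That was fixed in advance, because their groups of arrays do not overlap. None of those with a value under another setting changed sign there. The counts of genes past the threshold (117, with 71 higher and 46 lower) depended on the setting. They were 561, 349 and 212 with all probe sets tested (more rows than genes), 294, 152 and 142 on the mean of probe sets, and 385, 217 and 168 with array weights. At an adjusted p of 0.1 they were 213, 119 and 94, and at 0.01 they were 37, 25 and 12. With the retinal marker covariate, which takes a degree of freedom, they were 28, 18 and 10. Without moderation 76 passed and 27 were lower, and among genes above the median level 70 were lower. On the mean of probe sets without control 4 they were 853, 338 and 515, with more genes lower than higher. The causes of these shifts were not tested. With 1 array left out, the counts ran from 33 to 260 past, 20 to 159 higher and 13 to 101 lower, and the highest of each came without control 4. The Dicer1 log2 fold change ran from -0.169 to 0.0338 over those fits, the highest without control 4, was -0.268 (SE 0.133) with the retinal marker covariate, and did not pass under any setting run. The melanin list (adjusted p = 0.0443) passed in 12 of 20 alternatives. It gave 0.0575 among genes above the lower quartile, 0.0533 without moderation, 0.558 with an estimated correlation, 0.0852 by fry and 0.112 on the mean of probe sets without control 4, and from 0.000907 to 0.0831 with 1 array left out. The let-7 target list (0.118) gave 0.046 by fry and from 0.0412 to 0.175 with 1 array left out, the lowest without Dicer1-deficient array 2, and adjusted p = 0.419 with an estimated correlation. Where a filter on dim genes left a list under 5 members it gave no value. The lists of RPE transport genes, photoreceptor genes and miR-204 or miR-211 targets passed under no setting of camera or of fry for 1 direction, with lowest values of 0.0638, 0.0627 and 0.157. Lists that did not pass at first but did under some settings were BMP, TGF-beta and FGF genes (8 of 19, lowest 0.0212), fibroblast genes (6 of 21, lowest 0.00107), lens genes (3 of 20, lowest 0.00961) and p53 genes (1 of 21, 0.0226 by fry), none of them with an estimated correlation. No paired analysis was possible because the replicate numbers are names given in accession order. With no detection calls, signal over background was not measured, and dim genes near the lower quartile of 4.63 are the least certain.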

Other observations

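The genes in the next paragraph were chosen after their values were seen, and so was the test on genes near Dicer1, whose criterion was also tightened after its result was seen.

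Further genes past the limma threshold, outside the lists, rose in Dicer1-deficient RPE. Kcnq5, a voltage-gated potassium channel gene, rose by 1.48 on the log2 scale and Pygl, the liver glycogen phosphorylase gene, by 1.33. Hkdc1, a hexokinase gene, rose by 1.16 and Galc, the gene of the lysosomal enzyme galactosylceramidase, by 1.13. Mmp11, a matrix metalloproteinase gene, rose by 1.40 and Itga3, an integrin subunit gene, by 1.05. Among those that fell were Hapln1, a link protein gene of the hyaluronan matrix (-1.09), Slc9a3r1, which encodes an apical scaffold protein (-0.92), and Nrcam, a cell adhesion gene (-0.84). No theme was tested for these genes.

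Genes near Dicer1 could carry linked variants of the floxed allele and so appear changed. Of the 100 measured genes nearest to Dicer1 on chromosome 12, 1 (Clmn, log2 fold change 0.71) passed the threshold, or 1% (exact 95% interval 0.0253% to 5.45%), against 2.36% of all other genes (Fisher's exact test, two-sided, p = 0.731). No excess was seen, but the interval includes the share of other genes and higher ones, so linked variants cannot be told apart from none at this number of genes.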
